A study of Homo sapiens with 60 samples.

How the data were processed

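RNA from HT29 cells treated for 24 h with 8 ethanol extracts at 3 doses, or with vehicle, was sequenced in 60 libraries. Per the labels, 1 µg of total RNA with a RIN above 7 went into each mRNA library, made with the MGIEasy RNA Directional kit and read as 100 bp paired ends on an MGI instrument. The sample labels give 0.1% DMSO as vehicle, whereas the series design gives 2%. The authors' notes name FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.3a and RSEM 1.3.3 with the human genome build GRCh38, and the gene annotation is not given in the sources used here. The deposited table holds expected counts per gene, not scaled to depth, for 60675 Ensembl gene IDs. Of its 270 columns, 210 belong to samples not analysed here, among them hot-water extracts and wortmannin. Of the values used, 91% were whole numbers, and all were rounded, which changed the total of a library by at most 0.00022%. Of the gene IDs 93.2% had a symbol in the reference table and 94% were in GENCODE 29, which gave the coordinates.

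Libraries were grouped by extract and dose as the labels give them. Genes with at least 0.5 CPM in at least 3 libraries were tested, which left 16022. In edgeR 4.0.16 under R 4.3.3, libraries were scaled by TMM and a quasi-likelihood negative binomial model with a mean for each of 25 groups was fitted to all 60 libraries, with 35 residual degrees of freedom and a common dispersion of 0.00613, a biological coefficient of variation of 7.83%. Comparisons of 3 kinds were made within this model: each dose against vehicle, high against low dose of each extract, and the extracts of a library set against each other at high dose. The p-values were adjusted over the tested genes of each comparison by the method of Benjamini and Hochberg, with a threshold of 0.05. CPM values are group means with the SD over libraries, log2 changes come from the model, and their standard errors are the size of the change over the square root of its F statistic. Where a group had 1 library, its spread was assumed to be that of the other groups.

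A set of 28 gene lists was tested on log2 CPM, with a prior count of 2, by camera of limma 3.58.1 at a preset correlation between genes of 0.01, again with the correlation estimated for each list, and by fry. Their p-values were adjusted over all lists and extracts within a kind of comparison. Each estimated correlation came from all libraries in the fit, among them Zizyphi Fructus medium replicate 3, a library that stands apart. Calls kept or lost with an estimated correlation can therefore depend on that library. Counts of list genes are over all tested genes unless they are given as adjusted over the list alone, where the adjustment covered the genes of the list only. The lists, the comparisons, the tests and the rule for named genes were fixed before the data were examined. Named genes had a symbol and a mean log2 CPM of at least 1 and passed against vehicle and, with the same sign, from low to high dose. The 6 largest rises and the 6 largest falls against vehicle were taken, filled from the vehicle comparison alone where fewer passed both, then up to 4 members of each list with the largest change past the threshold. For high against low dose and for pairs of extracts, the 4 largest changes in each direction were taken. Of these, the text gives a part, and some results are not reported here. The 200 genes of smallest p in each direction from low to high dose of Coptidis Rhizoma were tested in the other extracts by camera.

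The depth of the libraries ran from 18.1 to 36.7 M counts, and 3 counts, taken as the floor of detection, corresponded to 0.082 to 0.17 CPM. Intervals of shares are 95% Wilson intervals, and intervals and floors cover counting error only. Reads of genes close in sequence or overlapping in position can be shared, as for AKR1C1 and AKR1C2, for UGT1A1 and UGT1A10, which have exons in common, and for the metallothioneins, and the level of an antisense RNA such as IGFL2-AS1 depends on the strand having been kept in counting. To simulate changes, counts for all 60 libraries were drawn from a common mean profile at the depth and estimated spread of these libraries. No difference between library sets, trend on GC content or library that stands apart was put in, so the recovery and false calls leave those out. Changes in both directions were put into 67 genes at 1.5-fold, 67 at 2-fold and 66 at 4-fold, all with a mean log2 CPM over 1. Recovery of genes of lower level, or where far more genes change as with Coptidis Rhizoma, was not tested. The method was then tested on these drawn counts. From low to high dose it recovered, at 3 libraries against 3, 85.1% of genes changed 1.5-fold and 97% of those changed 2-fold, with 12 false calls, at 2 against 2 71.6% and 97%, with 9, and at 1 against 1 50.7% and 80.6%, with 7. Against vehicle it recovered 88.1% and 100% at 3 against 3, or 71.6% and 98.5% with the compared groups fitted alone.

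Alternatives changed one choice at a time: the size factors of DESeq2 1.42.0, its Wald test, no filter on low counts, a fit of the compared groups alone, a replicate block, a replicate block within library sets, and leaving out each library in turn. Further alternatives, chosen after seeing the data, left out Zizyphi Fructus medium replicate 3, left out each vehicle library in turn in the tests of gene lists against vehicle, or removed each library's trend on GC content and transcript length, fitted by lowess, for the 15913 genes with both values. For comparisons with 3 libraries a side, the other splits of the libraries were run. Figures were drawn with python 3.11.15.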

Results

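RNA sequencing measured gene expression in HT29 cells, an established human colorectal cancer line, after 24 h with 70% ethanol extracts of 6 single herbs and of 2 herbal formulas, Yijung-tang and Banhasasim-tang. Each of the 8 extracts was given at 3 doses, and 3 libraries came from cells with vehicle. Each dose had 3 libraries for Citri Unshius Pericarpium, Cimicifugae Rhizoma, Bupleuri Radix and Aconiti Lateralis Radix Preparata, 2 for Coptidis Rhizoma, Zizyphi Fructus and Yijung-tang, and 1 for Banhasasim-tang. The high, medium and low doses were 500, 100 and 20 µg/mL, except 320, 64 and 12.8 µg/mL for Coptidis Rhizoma and 310, 62 and 12.4 µg/mL for Bupleuri Radix. The 60 libraries held 18.1 to 36.7 M counts each, with a median of 24.1 M, and 16022 genes were tested. The sample labels number the libraries in sets, with the vehicle in a set of its own and a pair of extracts in each other set. A difference from vehicle therefore cannot be told apart from a difference between sets, whereas high against low dose, and one extract against the other of its set, lie within a set. Gene levels are given as CPM, counts scaled to a common library size, with the SD, and log2 changes with their standard error. The p-values of genes measure only the spread between these libraries, which the labels do not describe as separate cultures. The camera p-values of lists instead compare the genes of a list with all other tested genes. They rest on the correlation taken between genes and can be small with few or no genes past the threshold.

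Coptidis Rhizoma, at high dose, had the most genes past the threshold among the 8 extracts. The question for each extract is which genes differ from vehicle and from its own low dose. CYP1A1 (ENSG00000140465, GRCh38 chromosome 15, 74719542 to 74725610), a cytochrome P450 induced through the aryl hydrocarbon receptor, stood at 258 ± 8.9 CPM (n = 2) against 0.46 ± 0.051 CPM in vehicle (n = 3), a log2 rise of 9.11 ± 0.18 (adjusted p = 5.6e-34). Its log2 change from vehicle was 2.25 at low and 5.70 at medium dose, and the rise from low to high dose was 6.87 ± 0.18 (adjusted p = 2.9e-29). CYP1B1, a related P450, went from 48.2 to 514 CPM, and TIPARP, a receptor target that limits the receptor's activity, from 64.9 to 304 CPM. In the list of aryl hydrocarbon receptor targets, 7 of 8 tested genes rose from low to high dose (list adjusted p = 1.93e-06).

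Genes of the amino acid stress response were among the largest rises. CHAC1 (ENSG00000128965, chromosome 15, 40952962 to 40956519), which breaks down glutathione, rose from 2.85 ± 0.37 to 84.2 ± 3.4 CPM, a log2 change of 4.89 ± 0.15 against vehicle (adjusted p = 1.8e-27). The glycine transporter SLC6A9 (ENSG00000196517, chromosome 1, 43991500 to 44031467) rose by 6.74 ± 0.18, the stress-induced NIBAN1 (ENSG00000135842, chromosome 1, 184790724 to 184974550) by 5.39 ± 0.13, and the transcription factors ATF3 and DDIT3 by 4.24 ± 0.14 and 3.88 ± 0.11. Of 21 tested ATF4-linked genes, 20 rose from low to high dose, with a median log2 change of 2.15 (list adjusted p = 3.3e-18). HMOX1 (ENSG00000100292, chromosome 22, 35380361 to 35394214), the haem-degrading enzyme and an NRF2 target, stood at 82.5 ± 3.7 against 8.65 ± 0.49 CPM, a rise of 3.26 ± 0.12. The NRF2-regulated cystine transporter SLC7A11 rose 6.60-fold and the aldo-keto reductase AKR1C1 9.35-fold, and in the NRF2 list 17 genes rose and 1 fell of 20 (list adjusted p = 1.7e-10).

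Cholesterol synthesis and DNA replication genes fell with Coptidis Rhizoma. Of 24 cholesterol genes, 23 fell from low to high dose (list adjusted p = 2.14e-15), among them HMGCS1, the cytosolic HMG-CoA synthase, from 256 ± 16 CPM in vehicle to 59.9 ± 2.5, and INSIG1, a sterol sensor, from 180 ± 2.1 to 39.7 ± 0.41. In fatty acid synthesis 8 genes fell and 1 rose of 10 (list adjusted p = 0.000446), including fatty acid synthase, FASN, at 0.399 times its vehicle level. All 24 DNA replication genes fell, with a median log2 change of -1.53 (list adjusted p = 5e-22), such as the helicase subunit MCM4, at 82.4 ± 2.8 against 322 ± 6.2 CPM, and cyclin E2, CCNE2, at 2.09 ± 0.35 against 12.4 ± 1.3. CDKN1A, a cyclin-dependent kinase inhibitor, rose 5.94-fold. In the mitosis list 18 genes fell and 1 rose of 24, or 19 and 1 adjusted over the list alone, but the call of the list (adjusted p = 0.000337) was lost at adjusted p = 0.0931 with an estimated correlation.

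The lists of interferon response, of NF-kappaB and chemokines, and of MAPK feedback and immediate early genes rose with the same extract. All 20 interferon response genes rose from low to high dose with a median log2 change of 1.62 (list adjusted p = 2.99e-12), and the antiviral GTPase MX1 stood at 61 ± 5.6 against 9.33 ± 0.87 CPM in vehicle. In the NF-kappaB and chemokine list 11 of 16 rose (list adjusted p = 7.85e-05), including LCN2, an iron-binding secreted protein, at 357 ± 1.9 against 86.9 ± 5.2 CPM. Of 21 MAPK feedback and immediate early genes 18 rose and 1 fell (list adjusted p = 7.46e-09), among them the EGF receptor ligands EREG, 5.92-fold, and AREG, 4.95-fold. The angiogenic factor VEGFA rose 7.07-fold, while CA9, a hypoxia-induced carbonic anhydrase, fell to 0.193 times vehicle.

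Secretory and stem cell genes of the intestine fell. Of 16 goblet and secretory genes 14 fell (list adjusted p = 9.18e-05), including ATOH1, the transcription factor that specifies secretory cells, at 0.298 ± 0.05 against 4.62 ± 0.15 CPM, and the mucin MUC2, at 6.64 ± 0.32 against 33.4 ± 5.4. In the list of WNT targets and stem cell genes 9 fell and 1 rose of 15 (list adjusted p = 0.00547), with the stem cell receptor LGR5 at 0.323 and CD44 at 0.257 times vehicle. The tight junction protein CLDN2 fell from 126 ± 4.7 to 14.1 ± 0.15 CPM. Among the largest falls, the nuclear receptor NR0B2 (ENSG00000131910, chromosome 1, 26911489 to 26913966) and the intestinal surface antigen GPA33 (ENSG00000143167, chromosome 1, 167052836 to 167166479) changed by -5.42 ± 0.29 and -5.16 ± 0.33, to levels near that of 3 counts in a library, so that the size of both is uncertain.

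For Coptidis Rhizoma 10078 genes passed against vehicle at high dose, 4955 higher and 5123 lower, and 9001 from low to high dose, 4449 higher and 4552 lower. Of these, 8220 passed both with the same sign, and 1077 rose and 1405 fell at least 2-fold from low to high dose. The 10078 genes are the larger part of the 16022 tested, whereas TMM scaling takes most genes as unchanged. Rises and falls with this extract are therefore relative to the other genes of a library, and the size factors of DESeq2 share that assumption. The counts adjusted over each list alone were those given, except in the mitosis list and in the NRF2 list, where 2 genes fell in place of 1. All lists given here as changed, other than mitosis, also passed with an estimated correlation, NRF2 targets at adjusted p = 0.0455.

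**Figure D1:**
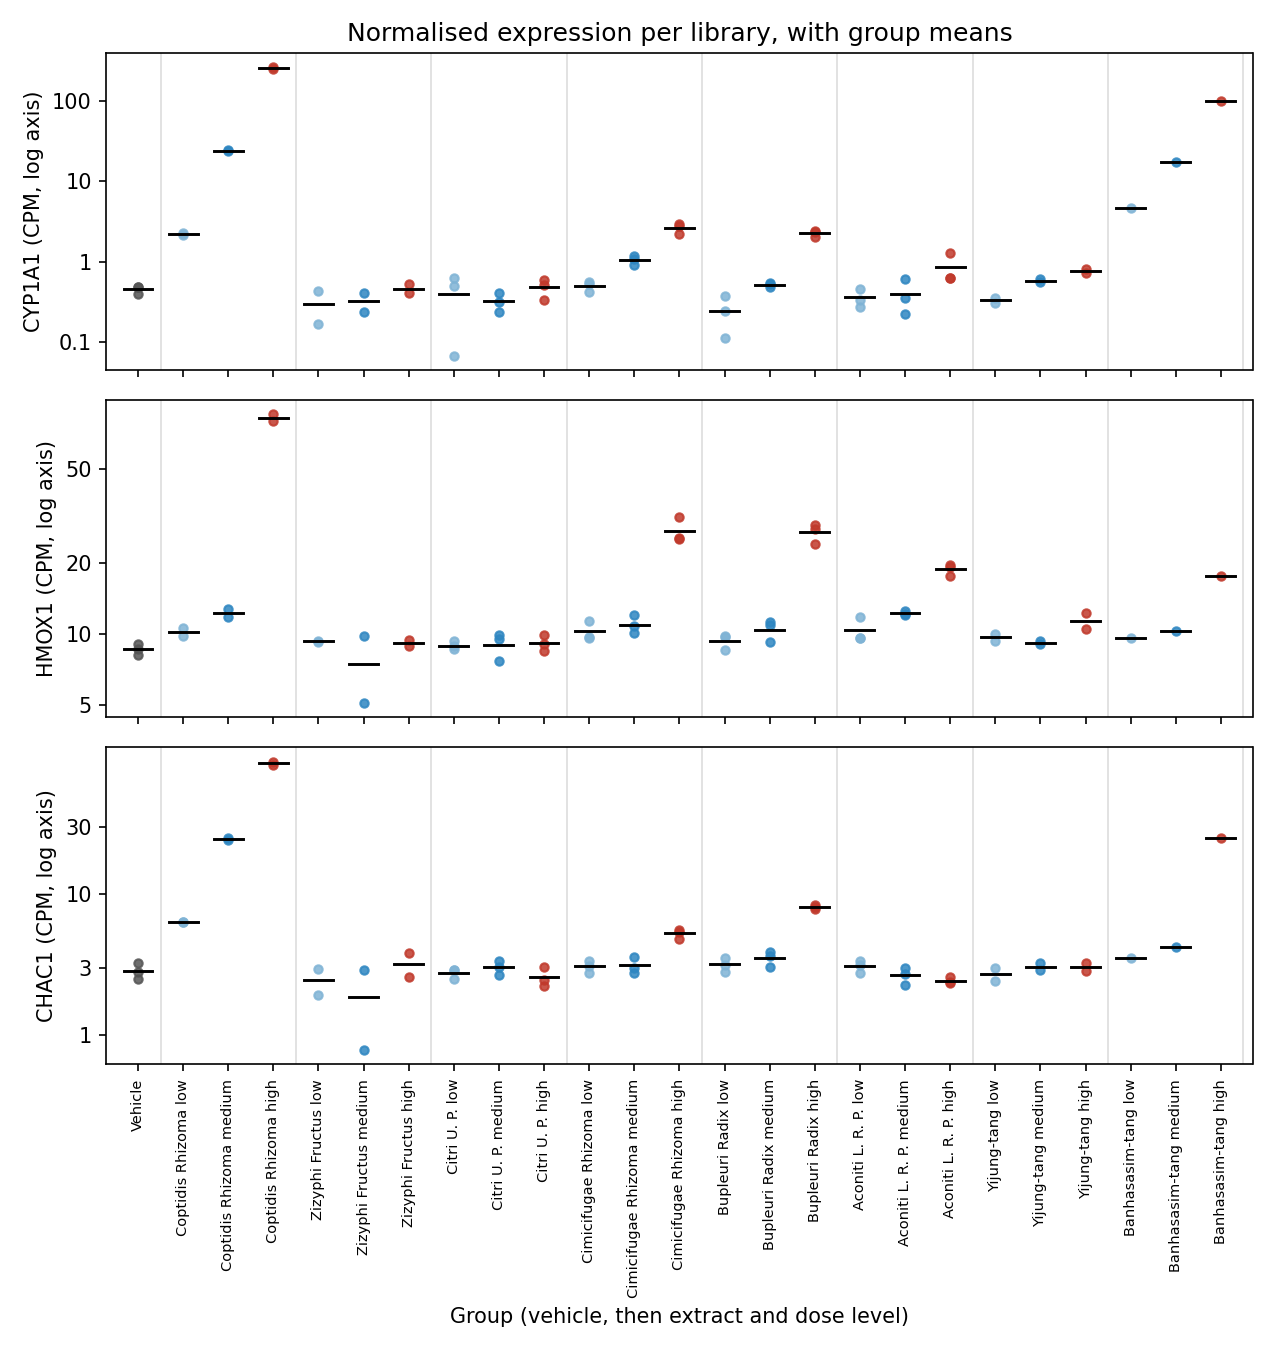
CYP1A1, HMOX1 and CHAC1 in CPM on a log axis, with a point for each library and a bar for each group mean (vehicle grey, low dose light blue, medium dose blue, high dose red). For Coptidis Rhizoma the high-dose means are 258, 82.5 and 84.2 CPM against 0.46, 8.65 and 2.85 CPM in vehicle.

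Banhasasim-tang, with 1 library per dose assumed to vary like the other groups, raised aryl hydrocarbon receptor and amino acid stress genes at 500 µg/mL. CYP1A1 stood at 102 CPM against 0.46 ± 0.051 in vehicle, a log2 rise of 7.78 ± 0.2 (adjusted p = 1e-29), and rose by 4.46 ± 0.23 from low to high dose. CYP1B1 rose 7.71-fold against vehicle and ALDH3A1, an aldehyde dehydrogenase of the same receptor's targets, 2.59-fold. CHAC1 stood at 24.7 against 2.85 CPM, asparagine synthetase, ASNS, at 234 against 59.9, and DDIT4, a stress-induced inhibitor of mTOR signalling, at 92.9 against 20.1. SLC7A11 rose 2.86-fold and EREG 2.34-fold, and VEGFA changed by 1.00 ± 0.07 on the log2 scale (adjusted p = 5.8e-15). The neurotrophin BDNF changed by -2.60 ± 0.31 (adjusted p = 6.9e-08), TXNIP, a glucose-responsive regulator of thioredoxin, by -1.38 ± 0.08 and the NADPH oxidase NOX1 by -1.14 ± 0.11.

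Each dose of Banhasasim-tang had 1 library, so that the tests of its genes take their spread from the other groups. The list tests by camera compare list genes with all other tested genes, so their p-values do not measure a spread between libraries of this extract. From low to high dose 17 of 21 ATF4-linked genes rose, or 19 adjusted over the list alone (list adjusted p = 5.02e-57). In the list of aryl hydrocarbon receptor targets 5 of 8 rose, or 7 adjusted over the list alone (list adjusted p = 9.03e-29), and in the NRF2 list 12 of 20, or 17 adjusted over the list alone (list adjusted p = 3.75e-36). Cholesterol genes fell as a list (adjusted p = 6.69e-14), with 3 of 24 past the threshold, or 9 adjusted over the list alone. INSIG1 was lower by -0.51 ± 0.09 and HMGCS1 by -0.60 ± 0.14 on the log2 scale. Of 21 MAPK feedback genes 2 rose, or 3 adjusted over the list alone (list adjusted p = 0.00133). These 5 lists also passed with an estimated correlation, whereas the interferon list, with 0 genes past the threshold in edgeR and 2 lower adjusted over the list alone, passed at adjusted p = 0.00112 and not at adjusted p = 0.241 with an estimated correlation. Against vehicle 1218 genes passed, 791 higher and 427 lower, and 277 from low to high dose, 166 higher and 111 lower, with 221 in both at the same sign. The first count was 808 without vehicle replicate 1, 112 with the compared groups fitted alone and 3015 without Zizyphi Fructus medium replicate 3, a library that stands apart, and the last fit gave 611 from low to high dose. Fitted alone, INSIG1 and HMGCS1 missed the threshold against vehicle, at adjusted p = 0.0861 and 0.105.

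Both ribosomal RNAs of the mitochondrion took a larger share of counts with these 2 extracts, a measure chosen after the values were seen. In Banhasasim-tang at high dose MT-RNR1 stood at 25900 against 1310 ± 85 CPM in vehicle (log2 change 4.30 ± 0.24, adjusted p = 3.1e-17) and MT-RNR2 at 82300 against 9950 ± 560 (3.05 ± 0.31, adjusted p = 9e-10). Their joint share of counts was 10.2% at high dose (95% Wilson interval 10.19 to 10.21), 2.073% at medium dose (2.068 to 2.079) and 1.11% at low dose (1.106 to 1.114), against 1.111% ± 0.0406 in vehicle. With Coptidis Rhizoma the order of doses was the opposite, with 10.15% ± 0.508 at low, 6.355% ± 0.127 at medium and 1.602% ± 0.053 at high dose (n = 2 each). At low dose of that extract MT-RNR1 changed by 4.13 ± 0.22 (adjusted p = 2.2e-17) and MT-RNR2 by 3.10 ± 0.27 (adjusted p = 1.1e-10). The mitochondrial mRNA of cytochrome oxidase subunit 3, MT-CO3, changed by -1.80 ± 0.28 there (adjusted p = 7.2e-05) and that of MT-ND5, a complex I subunit, by 1.58 ± 0.34 (adjusted p = 0.0029). Fractions of this kind carry counting intervals only, which leave out any spread between libraries.

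**Figure D2:**
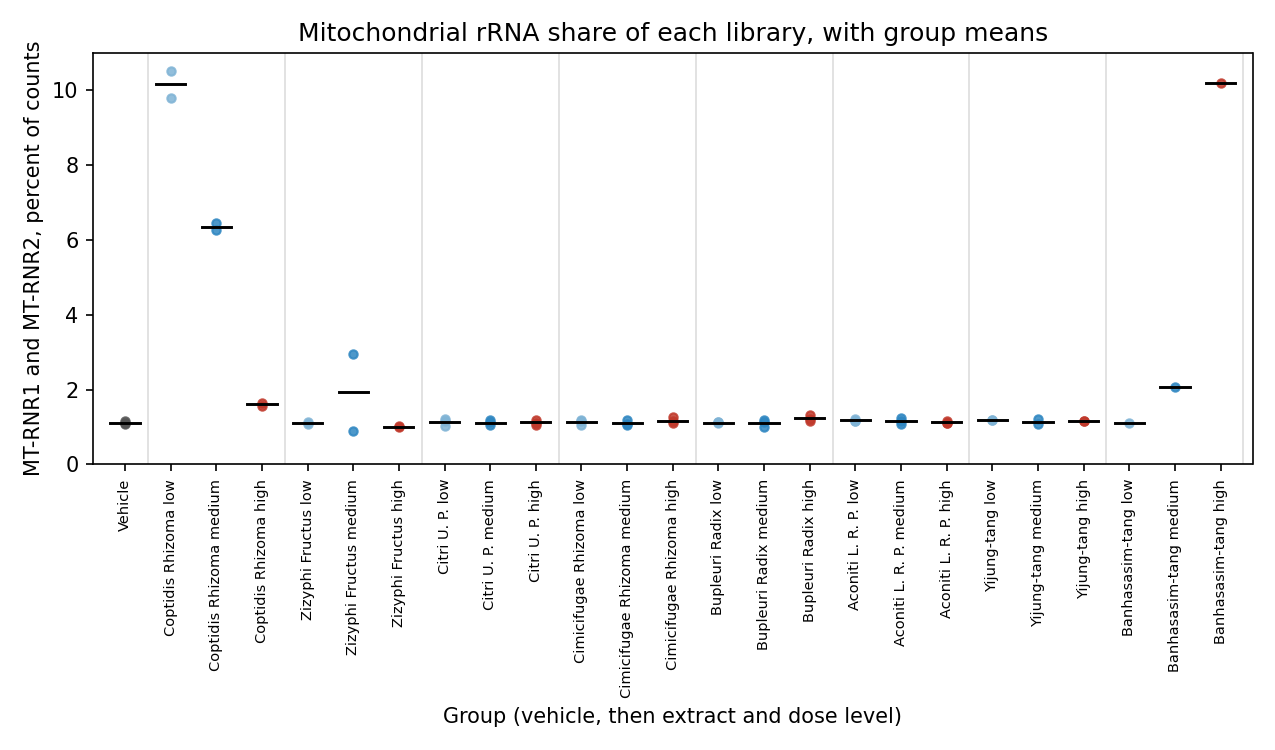
Share of all counts in MT-RNR1 and MT-RNR2 in percent, with a point for each library, by extract and dose. Coptidis Rhizoma at low dose (mean 10.15%) and Banhasasim-tang at high dose (10.2%) lie above the vehicle mean of 1.111%.

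Bupleuri Radix raised antioxidant, lysosomal and protein-folding genes at 310 µg/mL. HMOX1 stood at 27 ± 2.5 CPM (n = 3) against 8.65 ± 0.49 in vehicle, a log2 rise of 1.64 ± 0.11 (adjusted p = 1.8e-14), and the autophagy receptor SQSTM1 at 1040 ± 40 against 389 ± 17 (1.41 ± 0.05, adjusted p = 1.6e-23). CYP1A1 rose to 2.27 ± 0.2 CPM, 4.89-fold over vehicle and 9.59-fold over low dose, and AKR1C2, a steroid-reducing enzyme close to AKR1C1, rose 2.62-fold over vehicle. The low-dose level of CYP1A1 thus lay under vehicle, not far above that of 3 counts in a library. The size of its rise over low dose is therefore uncertain. DUSP5, a nuclear phosphatase of ERK, rose 3.30-fold, the amino acid transporter SLC38A4 3.79-fold and the antisense RNA IGFL2-AS1 4.56-fold. NOX1 fell from 18.7 ± 1 to 6.37 ± 0.49 CPM, the cholesterol exporter ABCG1 to 0.318 and the sodium-glucose transporter SLC5A9 to 0.231 times vehicle. The goblet cell genes REG4 and TFF3 fell to 0.444 and 0.482 times vehicle.

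In the NRF2 list 19 of 20 genes rose from low to high dose of Bupleuri Radix with a median log2 change of 0.86 (list adjusted p = 2.1e-42), and 7 of 8 aryl hydrocarbon receptor targets rose (list adjusted p = 3.6e-13). Of 23 lysosome and autophagy genes 14 rose, or 16 adjusted over the list alone (list adjusted p = 3.61e-16). Endoplasmic reticulum chaperones rose in 10 of 18, or 11 adjusted over the list alone (list adjusted p = 7.87e-10), with HERPUD1, of the unfolded protein response, 1.52-fold over vehicle. Of 15 heat shock genes 7 rose, or 10 adjusted over the list alone (list adjusted p = 4.44e-06), and of 21 ATF4-linked genes 13, or 16 adjusted over the list alone (list adjusted p = 1.23e-13), such as ATF3, 2.84-fold over vehicle. In the list of fatty acid oxidation and PPAR targets 7 rose and 1 fell of 15 (list adjusted p = 1.35e-05), with the lipid droplet protein PLIN2 2.27-fold over vehicle, while in fatty acid synthesis 3 of 10 fell, or 4 adjusted over the list alone (list adjusted p = 0.00211). In drug metabolism and efflux 6 rose and 1 fell of 10 (list adjusted p = 8.13e-05).

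NF-kappaB and chemokine genes rose in 7 of 16 with Bupleuri Radix, or 8 adjusted over the list alone (list adjusted p = 9.24e-05), among them the chemokine CXCL8, 1.93-fold, and the adhesion molecule ICAM1, 1.75-fold over vehicle. Of 21 MAPK feedback genes 8 rose, or 9 with 1 lower adjusted over the list alone (list adjusted p = 1.28e-05). Of 16 goblet and secretory genes 7 fell, or 8 adjusted over the list alone (list adjusted p = 0.000133). Interferon genes fell in 10 of 20, or 13 adjusted over the list alone, with OAS2, an antiviral enzyme, at 0.527 times vehicle. That list passed at adjusted p = 8.91e-08 but not at adjusted p = 0.0517 with an estimated correlation, and metallothioneins, with 2 of 7 lower or 3 adjusted over the list alone, passed at adjusted p = 0.0236 but not at adjusted p = 0.102 with an estimated correlation. The other lists named for Bupleuri Radix passed both ways. Against vehicle 4331 genes passed, 2296 higher and 2035 lower, and 2071 from low to high dose, 1015 higher and 1056 lower, with 1411 in both at the same sign. The vehicle count was 2614 without vehicle replicate 1, and the count between doses was 3636 with the compared groups fitted alone and 3624 without Zizyphi Fructus medium replicate 3.

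Cimicifugae Rhizoma raised antioxidant and aryl hydrocarbon receptor genes at 500 µg/mL. HMOX1 stood at 27.4 ± 3.4 CPM (n = 3) against 8.65 ± 0.49 in vehicle, a log2 rise of 1.66 ± 0.12 (adjusted p = 7.5e-14), and rose by 1.41 ± 0.11 from low to high dose. CYP1A1 rose to 2.64 ± 0.4 CPM (2.50 ± 0.26 over vehicle, adjusted p = 5.3e-09) and CYP1B1 1.95-fold. GCLM, a subunit of the enzyme that starts glutathione synthesis, rose 2.04-fold and SLC7A11 1.93-fold. AKR1C2 rose 2.05-fold over low dose, where its level lay under vehicle, and stood at 19.9 ± 0.61 CPM at high dose against 11.3 ± 0.21 in vehicle. NOX1 fell to 0.602 and the alcohol dehydrogenase ADH1C to 0.512 times their low-dose levels, which lay above vehicle by 0.27 and 0.68 on the log2 scale, and DPH6, of diphthamide synthesis, to 0.589 times vehicle. Against vehicle ADH1C, at -0.28 ± 0.16, did not pass (adjusted p = 0.245).

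In the NRF2 list 14 of 20 genes rose from low to high dose of Cimicifugae Rhizoma, or 18 adjusted over the list alone (list adjusted p = 9.02e-72), and in the aryl hydrocarbon receptor list 6 of 8, or 7 adjusted over the list alone (list adjusted p = 2.12e-33). Of 21 ATF4-linked genes 4 rose, or 6 adjusted over the list alone (list adjusted p = 8.96e-15), such as ASNS, 1.42-fold over vehicle. The endoplasmic reticulum chaperones had 1 of 18 higher, or 7 adjusted over the list alone (list adjusted p = 6.81e-12), the heat shock list 1 of 15 both ways (list adjusted p = 0.00025) and drug metabolism and efflux 3 of 10, or 4 with 1 lower adjusted over the list alone (list adjusted p = 4.96e-05). In the goblet list 1 of 16 fell (list adjusted p = 0.0235), AGR2, a disulfide isomerase of secretory cells, at 0.768 times vehicle. These 7 lists passed with an estimated correlation too, but the interferon list, with 0 genes past the threshold in edgeR, passed at adjusted p = 0.000352 and not at adjusted p = 0.202 with an estimated correlation. Against vehicle 2881 genes passed, 1647 higher and 1234 lower, and 140 from low to high dose, 70 higher and 70 lower, with 102 in both at the same sign. The vehicle count was 945 without vehicle replicate 1, 1574 without high replicate 3, 1712 with the compared groups fitted alone, 1307 with each library's trend on GC content and transcript length removed and 5271 without Zizyphi Fructus medium replicate 3. The count between doses was 91 without high replicate 1, 93 without high replicate 3, 84 without low replicate 2 and 378 without the Zizyphi Fructus library.

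Aconiti Lateralis Radix Preparata at 500 µg/mL raised part of the NRF2 list. HMOX1 stood at 18.9 ± 1.1 CPM (n = 3) against 8.65 ± 0.49 in vehicle (log2 change 1.13 ± 0.12, adjusted p = 3.4e-09) and AKR1C2 at 23.1 ± 0.75 against 11.3 ± 0.21 (1.03 ± 0.1, adjusted p = 6.5e-10). TUBA1A, an alpha-tubulin, rose 1.98-fold and CLIP4, a microtubule-binding protein, 1.68-fold over vehicle. DHRS2, a carbonyl reductase, fell from 8.27 ± 0.33 to 3.76 ± 0.14 CPM, the extracellular matrix protein THSD4 from 34.1 ± 5.7 to 18.1 ± 3.4, and CLDN2 to 0.699 times vehicle. The focal adhesion protein LPP fell to 0.492 and the synaptic scaffold SHANK2 to 0.432 times their low-dose levels, which stood at 0.35 and 0.36 over vehicle on the log2 scale.

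From low to high dose of Aconiti Lateralis Radix Preparata, 9 of 20 NRF2 targets rose, or 14 adjusted over the list alone (list adjusted p = 3.29e-25), and 2 of 8 aryl hydrocarbon receptor targets, or 4 adjusted over the list alone (list adjusted p = 0.000898). Fatty acid synthesis had 4 of 10 genes lower, or 6 adjusted over the list alone (list adjusted p = 2.29e-09), and the endoplasmic reticulum chaperones were lower as a list (adjusted p = 0.00234) with 0 of 18 past the threshold in edgeR. These lists passed with an estimated correlation, whereas cholesterol synthesis, with 1 of 24 lower, passed at adjusted p = 4.3e-05 but not at adjusted p = 0.0997 with an estimated correlation, and the interferon list, with 2 of 20 lower or 4 adjusted over the list alone, at adjusted p = 0.000102 but not at adjusted p = 0.158 with an estimated correlation. Against vehicle 2774 genes passed, 1498 higher and 1276 lower, and 434 from low to high dose, 76 higher and 358 lower, with 264 in both at the same sign. The vehicle count was 1242 without vehicle replicate 1, 1566 without high replicate 1 and 5170 without Zizyphi Fructus medium replicate 3. The count between doses was 269 without high replicate 1, 272 without high replicate 3, 1081 with the compared groups fitted alone and 1009 without the Zizyphi Fructus library.

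Citri Unshius Pericarpium at 500 µg/mL changed few genes between doses. The antisense RNA IGFL2-AS1 stood at 4.2 ± 0.17 CPM (n = 3) against 7.01 ± 0.6 in vehicle (log2 change -0.73 ± 0.12, adjusted p = 0.00014), whereas Bupleuri Radix raised it. The growth factor BMP2 fell to 0.710 and ACSS2, an acetyl-CoA synthetase, to 0.777 times vehicle. The chaperone HSPA5 rose 1.18-fold over vehicle, and its call between doses (adjusted p = 0.00016) was lost with no filter on low counts, at adjusted p = 0.14.

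Endoplasmic reticulum chaperones rose as a list from low to high dose of Citri Unshius Pericarpium (adjusted p = 1.83e-07), with 2 of 18 genes past the threshold, or 4 adjusted over the list alone. DNA replication (adjusted p = 1.42e-12) and mitosis genes (adjusted p = 8.91e-10) were higher and interferon genes lower (adjusted p = 1.06e-12) as lists, with median log2 changes of 0.10, 0.09 and -0.22. Each of these 3 lists had 0 genes past the threshold in edgeR, and adjusted over the list alone 4 replication genes were higher, 6 interferon genes lower and 0 mitosis genes changed. Cholesterol (adjusted p = 1.41e-08) and fatty acid synthesis (adjusted p = 0.000102) were lower as lists, with 0 of 24 and 1 of 10 past the threshold, or 1 and 3 adjusted over the list alone, and the heat shock list was higher with 0 of 15 both ways (adjusted p = 0.00153). These 7 lists passed with an estimated correlation. Against vehicle 2116 genes passed, 1219 higher and 897 lower, but 23 from low to high dose, 3 higher and 20 lower, with 16 in both at the same sign. The vehicle count was 458 without vehicle replicate 1, 1030 without high replicate 2, 1038 without high replicate 3, 719 with the compared groups fitted alone, 718 with each library's trend on GC content and transcript length removed and 4686 without Zizyphi Fructus medium replicate 3. The count between doses was 15 without high replicate 1, 11 without high replicate 2, 9 without low replicate 2 and 11 without low replicate 3, and 51, 72, 74, 53 and 229 with the groups fitted alone, with the DESeq2 Wald test, with no filter on low counts, with those trends removed and without the Zizyphi Fructus library.

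Yijung-tang at 500 µg/mL raised some NRF2 and aryl hydrocarbon receptor targets. AKR1C2 stood at 16.7 ± 0.69 CPM (n = 2) against 11.3 ± 0.21 in vehicle (log2 change 0.57 ± 0.11, adjusted p = 0.001) and rose by 0.93 ± 0.13 from low to high dose (adjusted p = 2.5e-05). ALDH3A1 rose 1.73-fold over low dose, and the aldo-keto reductase AKR1B10 by 0.69 ± 0.08 on the log2 scale (adjusted p = 1.3e-06). Part of these 3 rises is a low-dose level under vehicle, by -0.37 for AKR1C2, -0.29 for ALDH3A1 and -0.32 for AKR1B10, and over vehicle the last 2 rose 1.42-fold and by 0.37 ± 0.07. ANXA13, an annexin of the intestinal epithelium, fell from 50.2 ± 1.9 in vehicle to 31.5 ± 1.6 CPM, and the urea transporter SLC14A1 fell to 0.581 times its low-dose level, which stood at 0.31 over vehicle on the log2 scale.

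In the NRF2 list 5 of 20 genes rose from low to high dose of Yijung-tang, or 13 adjusted over the list alone (list adjusted p = 4.13e-28), and in the aryl hydrocarbon receptor list 1 of 8, or 6 adjusted over the list alone (list adjusted p = 8.76e-16). Drug metabolism and efflux had 1 of 10 higher, or 3 adjusted over the list alone (list adjusted p = 0.000491), and fatty acid oxidation 1 of 15, or 3 adjusted over the list alone (list adjusted p = 0.00153). DNA replication genes were higher (adjusted p = 6.92e-07) and interferon genes lower (adjusted p = 1.48e-09) as lists, each with 0 genes past the threshold in edgeR, or 1 and 5 adjusted over the list alone. These 6 lists passed with an estimated correlation, but cholesterol synthesis, lower at adjusted p = 7.25e-07, did not, at adjusted p = 0.051 with an estimated correlation. Against vehicle 1225 genes passed, 747 higher and 478 lower, and 33 from low to high dose, 14 higher and 19 lower, with 24 in both at the same sign. The vehicle count was 335 without vehicle replicate 1, 1948 without vehicle replicate 3, 274 without high replicate 1, 226 without high replicate 2, 25 with the compared groups fitted alone, 765 with each library's trend on GC content and transcript length removed and 3497 without Zizyphi Fructus medium replicate 3. The count between doses was 13 without high replicate 1, 9 without high replicate 2, 10 without low replicate 1 and 13 without low replicate 2, and 316, 58, 98 and 163 with the groups fitted alone, with the DESeq2 Wald test, with no filter on low counts and without the Zizyphi Fructus library. Of the genes named, ANXA13 missed the threshold between doses without high replicate 2, at adjusted p = 0.051.

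Zizyphi Fructus gave no gene past the threshold between its doses. Against vehicle LGR5 stood at 40.2 ± 1.1 CPM (n = 2) against 28.7 ± 1.7 (log2 change 0.48 ± 0.07, adjusted p = 1.9e-05) and ABCG2, a drug efflux pump, at 102 ± 3 against 77.8 ± 6.3 (0.39 ± 0.05, adjusted p = 4.6e-06). Both stood above vehicle at low dose too, by 0.41 (adjusted p = 0.00026) and 0.22 (adjusted p = 0.0058). Their differences between doses, 0.07 ± 0.07 and 0.17 ± 0.05, did not pass at an adjusted p of 1. At high dose LGR5 was above vehicle also with Citri Unshius Pericarpium by 0.37 ± 0.06, with Cimicifugae Rhizoma by 0.33 ± 0.06 and with Yijung-tang by 0.56 ± 0.07. With the compared groups fitted alone both missed the threshold, at adjusted p = 0.105 and 0.125. Aryl hydrocarbon receptor (adjusted p = 0.00214) and NRF2 targets (adjusted p = 0.000312) were higher and interferon genes lower (adjusted p = 1.88e-07) as lists from low to high dose, with 0 genes past the threshold in edgeR in each. None of the 3 passed with an estimated correlation, at adjusted p = 0.0517, 0.257 and 0.0573, or by fry, at adjusted p = 0.106, 0.375 and 0.109, but all 3 did with the replicate block. From low to high dose edgeR called 0 genes, with 331 at an unadjusted p under 0.05, and DESeq2 called 0, while 44 passed with no filter on low counts and 10 with the groups fitted alone. Against vehicle 1106 genes passed, 701 higher and 405 lower, which was 210 without vehicle replicate 1, 1862 without vehicle replicate 3, 426 without high replicate 2, 91 without high replicate 3, 12 with the groups fitted alone, 447 with each library's trend on GC content and transcript length removed and 3390 without Zizyphi Fructus medium replicate 3.

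Extracts of a set were compared with each other at high dose. Coptidis Rhizoma and Zizyphi Fructus differed in 9098 genes, 4490 higher and 4608 lower in the former, with CYP1A1 at 258 ± 8.9 against 0.461 ± 0.084 CPM (n = 2 each, log2 difference 9.10 ± 0.22, adjusted p = 1.3e-30), and SLC6A9 higher by 6.24 ± 0.21. Bupleuri Radix and Aconiti Lateralis Radix Preparata, at 310 and 500 µg/mL, differed in 3381, 1641 higher and 1740 lower in the former, with DUSP5 at 14 ± 1.3 against 3.91 ± 0.45 CPM (n = 3 each, 1.83 ± 0.12, adjusted p = 9.1e-15), the protein kinase A inhibitor PKIB at 31.4 ± 2.7 against 10.7 ± 0.71 and NOX1 at 6.37 ± 0.49 against 22.6 ± 0.81. Citri Unshius Pericarpium and Cimicifugae Rhizoma differed in 145, 28 higher and 117 lower in the former, with HMOX1 at 9.16 ± 0.74 against 27.4 ± 3.4 CPM (n = 3 each, -1.58 ± 0.12, adjusted p = 4.5e-13), CYP1A1 different by -2.45 ± 0.26 and AKR1C2 by -1.23 ± 0.1. Yijung-tang (n = 2) and Banhasasim-tang (n = 1) differed in 252, 75 higher and 177 lower in the former, with CYP1A1 at 0.769 ± 0.072 against 102 CPM (-7.05 ± 0.22, adjusted p = 4.1e-26), CHAC1 at 3.04 ± 0.27 against 24.7 and ADH1C at 2.84 ± 0.068 against 0.944. The third count was 94 without Citri Unshius Pericarpium high replicate 2 and 340 without the Zizyphi Fructus library, and the fourth 149 without Yijung-tang high replicate 2, 1556 with the groups fitted alone and 647 without the Zizyphi Fructus library. The second was 5345 with the groups fitted alone and 5256 without the Zizyphi Fructus library.

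The 200 genes that rose and the 200 that fell with the smallest p from low to high dose of Coptidis Rhizoma were followed in the other extracts. Of the 200 that rose, 76.5% were higher at the high dose of Banhasasim-tang (adjusted p = 8.29e-38), 71% of Bupleuri Radix (adjusted p = 3.37e-19) and 64% of Cimicifugae Rhizoma (adjusted p = 7.1e-14). Of the 200 that fell, 70% were lower with Banhasasim-tang (adjusted p = 1.46e-17), 64% with Bupleuri Radix (adjusted p = 6.51e-11) and 55% with Cimicifugae Rhizoma (adjusted p = 0.000902). These 6 tests also passed with an estimated correlation. With Citri Unshius Pericarpium 30% of the genes that rose were higher, and the set moved the other way (adjusted p = 7.93e-09). With Aconiti Lateralis Radix Preparata the risen genes passed at adjusted p = 0.0325 but not at adjusted p = 0.152 with an estimated correlation, and the fallen genes at adjusted p = 0.00252. Neither set passed with Yijung-tang or Zizyphi Fructus. With the 50 genes of smallest p per direction, 4 of these calls ended. They were those of the fallen genes with Cimicifugae Rhizoma (52% lower, adjusted p = 0.0798, and 0.238 with an estimated correlation) and of the risen genes with Aconiti Lateralis Radix Preparata (adjusted p = 0.194). With an estimated correlation they were those of the fallen genes there (adjusted p = 0.168) and the risen genes with Citri Unshius Pericarpium (adjusted p = 0.132). Across all 16022 genes, which are not independent of each other, the Spearman rho of the log2 changes from low to high dose was highest for Cimicifugae Rhizoma and Bupleuri Radix, at 0.358. Their Pearson r, 0.092, was below that of Bupleuri Radix and Yijung-tang, 0.165, and of Coptidis Rhizoma and Banhasasim-tang, 0.164. Over genes called in either extract r was highest for Cimicifugae Rhizoma and Yijung-tang, at 0.81 for 151 genes, against 0.71 for 2083 genes in Cimicifugae Rhizoma and Bupleuri Radix.

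**Figure D3:**
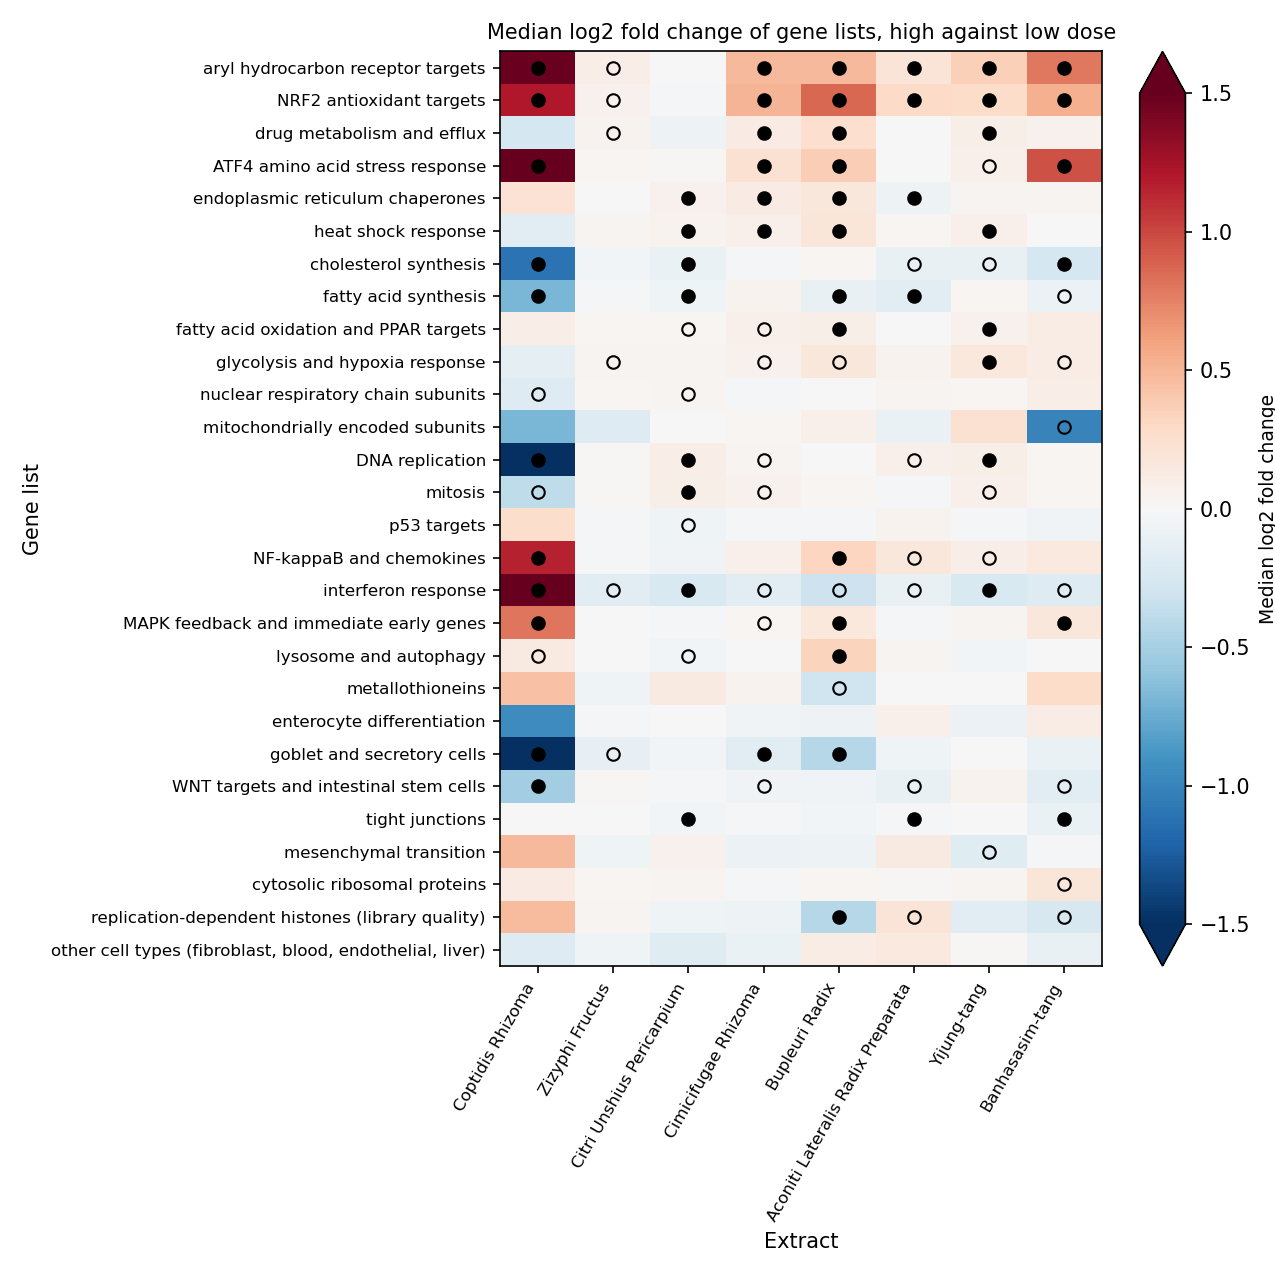
Median log2 change from low to high dose of the genes of each of 28 lists in 8 extracts, as colour from -1.5 to 1.5. A filled circle marks a list that passed with the preset and with an estimated correlation, an open circle one that passed with the preset alone. Estimated correlations came from all 60 libraries, Zizyphi Fructus medium replicate 3 among them.

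Genes of cytosolic ribosomal proteins, the protein part of the ribosome, were lower than in vehicle at high dose as a list of 32 in 6 extracts, with 13 of them past the threshold for Bupleuri Radix, or 16 adjusted over the list alone (list adjusted p = 6.11e-05), and 11 for Aconiti Lateralis Radix Preparata, or 14 adjusted over the list alone (list adjusted p = 5.86e-08). For Cimicifugae Rhizoma 10 passed, or 16 adjusted over the list alone (list adjusted p = 4e-07), for Citri Unshius Pericarpium 7, or 9 adjusted over the list alone (list adjusted p = 7.76e-06), for Yijung-tang 2 both ways (list adjusted p = 1.57e-06) and for Zizyphi Fructus 1, or 0 adjusted over the list alone (list adjusted p = 6.36e-05). None of these 6 calls held, at adjusted p = 0.48, 0.338, 0.371, 0.42, 0.39 and 0.48 with an estimated correlation. Vehicle replicate 1 had 6.8% of its counts in ribosomal protein genes, against 5.774% and 5.49% in the other vehicle libraries. Without it 2 genes passed for Bupleuri Radix and at most 1 for each of the other 5 extracts, and the list call ended for Zizyphi Fructus, at adjusted p = 0.0761. From low to high dose the list did not pass in any of the 6, at adjusted p = 0.0519 or more. The 13 subunits of the respiratory chain encoded in the mitochondrion all fell with Coptidis Rhizoma at high dose against vehicle (list adjusted p = 0.00361), a call lost at adjusted p = 0.554 with an estimated correlation. That correlation was estimated over all 60 libraries. Among them, Zizyphi Fructus medium replicate 3 had 38.81% of its counts in these genes, against 6.816% in the other library of its group. Its share of ribosomal protein genes was 2.582% against 5.393%. No list test was run without that library, so the calls lost with an estimated correlation do not settle whether these 2 lists moved. The same libraries gave the estimated correlations of the other lists, so calls of those lists kept or lost that way can depend on that library too. Over all lists, extracts and both high-dose comparisons 187 calls passed with the preset correlation and 98 of those tests with an estimated correlation. The fry test made 207 calls, and it asks whether the genes of a list move on balance one way, not whether they move more than other genes.

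At medium dose against vehicle CYP1A1 had changed by 5.70 on the log2 scale with Coptidis Rhizoma and by 5.23 with Banhasasim-tang, and CHAC1 by 3.10 and 0.56. The genes past the threshold against vehicle at medium dose numbered 3138 with Coptidis Rhizoma, 7849 with Zizyphi Fructus, 399 with Citri Unshius Pericarpium, 1390 with Cimicifugae Rhizoma, 2087 with Bupleuri Radix, 1504 with Aconiti Lateralis Radix Preparata, 519 with Yijung-tang and 352 with Banhasasim-tang. Without vehicle replicate 1 the medium-dose count was 1935 with Coptidis Rhizoma, 20 with Citri Unshius Pericarpium, 127 with Cimicifugae Rhizoma, 306 with Bupleuri Radix, 226 with Aconiti Lateralis Radix Preparata, 99 with Yijung-tang and 75 with Banhasasim-tang. Without vehicle replicate 2 the medium-dose count was 228 with Citri Unshius Pericarpium. Without vehicle replicate 3 the medium-dose count was 984 with Citri Unshius Pericarpium, 2274 with Cimicifugae Rhizoma, 2330 with Aconiti Lateralis Radix Preparata, 1190 with Yijung-tang and 951 with Banhasasim-tang. With Coptidis Rhizoma it was 1594 without medium replicate 2 and 1438 without medium replicate 3. With Zizyphi Fructus it was 1515 without medium replicate 3. With Citri Unshius Pericarpium it was 62 without medium replicate 1, 52 without medium replicate 2 and 775 without medium replicate 3. With Cimicifugae Rhizoma it was 734 without medium replicate 1 and 444 without medium replicate 3. With Bupleuri Radix it was 1364 without medium replicate 1, 1243 without medium replicate 2 and 1188 without medium replicate 3. With Aconiti Lateralis Radix Preparata it was 525 without medium replicate 2 and 933 without medium replicate 3. With Yijung-tang it was 49 without medium replicate 1 and 74 without medium replicate 2. The medium-dose count with each library's trend on GC content and transcript length removed was 183 with Citri Unshius Pericarpium, 648 with Cimicifugae Rhizoma and with Aconiti Lateralis Radix Preparata, 675 with Bupleuri Radix and 310 with Yijung-tang. In the Zizyphi Fructus library left out there, 41.77% of counts (95% Wilson interval 41.75 to 41.79) were mitochondrial, against 7.707% (7.696 to 7.718) in the other of its group, and with the compared groups fitted alone edgeR called 0 genes for that dose, with 1153 at an unadjusted p under 0.05, and DESeq2 in the fit of all libraries 7630.

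At low dose CYP1A1 stood above vehicle by 3.32 on the log2 scale with Banhasasim-tang (n = 1, adjusted p = 2.3e-10) and by 2.25 with Coptidis Rhizoma. The genes past the threshold against vehicle at low dose numbered 981 with Coptidis Rhizoma, 968 with Zizyphi Fructus, 2264 with Citri Unshius Pericarpium, 2172 with Cimicifugae Rhizoma, 2321 with Bupleuri Radix, 2320 with Aconiti Lateralis Radix Preparata, 1219 with Yijung-tang and 516 with Banhasasim-tang. Without vehicle replicate 1 the low-dose count was 316 with Coptidis Rhizoma, 180 with Zizyphi Fructus, 427 with Citri Unshius Pericarpium, 438 with Cimicifugae Rhizoma, 478 with Bupleuri Radix, 387 with Aconiti Lateralis Radix Preparata, 265 with Yijung-tang and 75 with Banhasasim-tang. Without vehicle replicate 3 the low-dose count was 1508 with Coptidis Rhizoma, 1689 with Zizyphi Fructus, 2053 with Yijung-tang and 1284 with Banhasasim-tang. With Coptidis Rhizoma it was 299 without low replicate 2 and 186 without low replicate 3. With Zizyphi Fructus it was 115 without low replicate 2 and 239 without low replicate 3. With Citri Unshius Pericarpium it was 1171 without low replicate 2 and 1284 without low replicate 3. With Cimicifugae Rhizoma it was 1029 without low replicate 2 and 1157 without low replicate 3. With Bupleuri Radix it was 1309 without low replicate 1 and 1202 without low replicate 2. With Aconiti Lateralis Radix Preparata it was 1077 without low replicate 1 and 1514 without low replicate 2. With Yijung-tang it was 251 without low replicate 1 and 270 without low replicate 2. The low-dose count with each library's trend on GC content and transcript length removed was 635 with Coptidis Rhizoma, 464 with Zizyphi Fructus, 886 with Citri Unshius Pericarpium, 983 with Cimicifugae Rhizoma, 978 with Bupleuri Radix, 1167 with Aconiti Lateralis Radix Preparata, 557 with Yijung-tang and 160 with Banhasasim-tang. With all libraries, 161 genes were higher and 73 lower in all 8 low-dose comparisons, which share the same 3 vehicle libraries. Within the sets, the low doses of Citri Unshius Pericarpium and Cimicifugae Rhizoma, and those of Bupleuri Radix and Aconiti Lateralis Radix Preparata, differed in 0 genes in edgeR, with 262 and 316 at an unadjusted p under 0.05. Those of Coptidis Rhizoma and Zizyphi Fructus differed in 28 genes, among them MT-RNR1 (log2 difference 4.43 ± 0.26, adjusted p = 1.1e-15), CYP1A1 (2.85 ± 0.37, adjusted p = 3.7e-06), CHAC1 (1.36 ± 0.21, adjusted p = 1e-04) and TXNIP (-1.11 ± 0.07, adjusted p = 1.3e-15). Those of Yijung-tang and Banhasasim-tang differed in 5, CYP1A1 (-3.80 ± 0.35, adjusted p = 1.4e-09), CYP1B1 (-1.40 ± 0.08), ALDH1A3 (-1.14 ± 0.11), TIPARP (-0.66 ± 0.09) and PIM1 (-0.65 ± 0.12). The genes of these 2 pairs were chosen after their values were seen.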

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

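Tests chosen only after the result was seen were those of the vehicle libraries as set apart, of low doses in pairs with fewer than 3 libraries, of a response to Zizyphi Fructus, of RNA from other cell types, of library set or run, of nuclear copies and of a full loss of mitochondrial mRNA. Effects of high against low dose differed between the extracts of each set, by a test of the difference itself. They differed in 6870 genes between Coptidis Rhizoma and Zizyphi Fructus, 3370 higher and 3500 lower in the former, with CYP1A1 at a difference of 6.25 ± 0.71 on the log2 scale (adjusted p = 1.4e-09). Between Bupleuri Radix and Aconiti Lateralis Radix Preparata they differed in 1365, 736 higher and 629 lower, with NOX1 at -1.74 ± 0.11 (adjusted p = 2.4e-15). Between Yijung-tang and Banhasasim-tang they differed in 74, 16 higher and 58 lower, with ASNS at -1.77 ± 0.11 (adjusted p = 1.9e-14). Between Citri Unshius Pericarpium and Cimicifugae Rhizoma they differed in 32, 3 higher and 29 lower, with HMOX1 at -1.38 ± 0.17 (adjusted p = 8e-07).

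Each extract differed from vehicle already at its low dose, with a median of 1695.5 genes over the extracts. As the source of most of these genes, a response particular to an extract is argued against for the 4 extracts with 3 libraries per dose, since 0 genes passed in edgeR between the low doses within their sets, with 262 and 316 at an unadjusted p under 0.05. Between Coptidis Rhizoma and Zizyphi Fructus, with 2 libraries each, 28 passed, with 540 at an unadjusted p under 0.05, against 981 and 968 from vehicle. This argues against it as the source of most genes there too, though not of all, with CYP1A1 among the 28. The 262, 316 and 540 lie under a share of 0.05 of the 16022 tested genes, so the test was strict in this fit. The fit also held Zizyphi Fructus medium replicate 3, and these pairs were not tested without it. The same fit called 2172 to 2321 genes at low dose of the 4 extracts against vehicle. Smaller numbers of genes particular to an extract are therefore not excluded. Between Yijung-tang and Banhasasim-tang 5 passed, CYP1A1 among them, but 1 library per dose of the latter leaves that pair undecided. Without vehicle replicate 1 the median was 351.5, without replicate 2 it was 1455.5 and without replicate 3 it was 2501, so that vehicle replicate 1 may account for a large part. After removal of each library's trend on GC content and transcript length the median was 760.5 against 1690.5 before, for the 15913 genes with both values, so that such a trend may account for part too. A response shared by all extracts stays open, and vehicle libraries prepared apart from the others cannot be told apart from these, since 0 extract libraries share the vehicle's library set.

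Zizyphi Fructus medium replicate 3 stood apart from all other libraries, with 41.77% of its counts mitochondrial (95% Wilson interval 41.75 to 41.79) against 3.66% to 15.5% in the others, and a TMM factor of 0.5665. A response to the extract is argued against by 7.707% (7.696 to 7.718) in the other library of its group. A loss of short transcripts is argued against as the whole cause by a Spearman rho of 0.171 between transcript length and the log2 ratio to that library, under the bound of 0.2 set for it, while the median log2 ratios did not follow length throughout, at -0.16 under 500 bp (234 genes), -0.33 from 500, -0.27 from 1000, -0.10 from 2000 and 0.09 from 4000 bp, and a smaller loss is not excluded. For RNA from other cell types, the median ratio of 8 tested markers to their median in the other libraries was 1. CD68 stood at 38.3 against 6.12 CPM, COL1A1 at 2.9 and CD14 at 0.589 times, and LYZ and SERPINA1, which HT29 libraries here hold in quantity, stood at 0.625 and 1.66 times. By the rule set for the 8 tested markers, a mixture of ratios over and under 2, as here, decides nothing. Without the TMM scaling used for these, the rest of the 21 markers stood at 0.214 CPM (HBA1) or less in every library, with PTPRC at most at 0.0913, COL3A1 at 0.0485, CDH5 at 0.0469 and ALB at 0.0801. The low levels of this rest argue against a large share of RNA from fibroblast, blood, endothelial or liver cells, and cell types without a marker here stay open.

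The mitochondrial rRNA share was raised in Coptidis Rhizoma at low and medium dose and in Banhasasim-tang at high dose, to 10.15%, 6.355% and 10.2% against 1.111% in vehicle. Library set or run is argued against, since the highest share among libraries of the other extract of the same sets was 2.96%. That was Zizyphi Fructus medium replicate 3, the library that stands apart, and the next was Yijung-tang medium replicate 1, at 1.201%. A move of reads assigned to nuclear copies is argued against for MT-RNR2, since the 13 counted held in vehicle 0.000501% of its rise. They held 0.352 CPM in vehicle and 0.43 CPM in Coptidis Rhizoma low dose. Expected counts divide reads that match several genes by the estimated levels of these genes, so such reads could not be told apart here. For MT-RNR1 the question stays open, since 0 annotated genes outside the mitochondrial genome share 31-base words with it, so that no copy was counted. A fall of mitochondrial mRNA, with or without growth along the heavy-strand transcript, is argued against, since a vehicle library that lost all of it would reach an rRNA share of 1.25% at most, while a Spearman rho of change and position over 12 genes, -0.06 for Coptidis Rhizoma at low and 0.15 for Banhasasim-tang at high dose, did not decide on such growth. A response to the extracts, and a change in how much mitochondrial rRNA the selection of mRNA let through, were not tested and stay open.

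Comparisons of 3 libraries with 3 have 10 splits, too few for a share under 0.05, and in each of the 18 comparisons run 1 of 10 splits, the real one, called as many genes with the groups fitted alone. For Citri Unshius Pericarpium the real value and the highest of the other splits were 719 against 0 at high, 8 against 1 at medium and 963 against 1 at low dose against vehicle, and 51 against 29 from low to high dose. For Cimicifugae Rhizoma the real value and the highest of the other splits were 1712 against 0 at high, 10 against 0 at medium and 537 against 1 at low dose against vehicle, and 157 against 2 from low to high dose. For Bupleuri Radix the real value and the highest of the other splits were 3838 against 0 at high, 504 against 0 at medium and 1072 against 0 at low dose against vehicle, and 3636 against 0 from low to high dose. For Aconiti Lateralis Radix Preparata the real value and the highest of the other splits were 2120 against 0 at high, 117 against 0 at medium and 1166 against 0 at low dose against vehicle, and 1081 against 0 from low to high dose. Between extracts at high dose they were 206 against 8 for Citri Unshius Pericarpium and Cimicifugae Rhizoma and 5345 against 0 for Bupleuri Radix and Aconiti Lateralis Radix Preparata.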

How the results depend on the processing

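Of these alternatives, the fit without the Zizyphi Fructus library, the correction for GC content and transcript length and the list tests against vehicle without each vehicle library were chosen after seeing the data. So were the pairs of extracts at medium dose and, at low dose, the pairs with fewer than 3 libraries in a group. The others were chosen before the data were examined. With the size factors of DESeq2 in the edgeR fit all 36 counts stayed within 1.5 times, and with the replicate block (replicate numbers as an additive term) all 37 counts did, the list calls numbering 191 with the block against 187. With the DESeq2 Wald test 30 of 36 counts stayed within 1.5 times and 6 were higher, and with no filter on low counts 29 did and 7 were higher. With the compared groups fitted alone 7 of 35 did, 21 being lower and 7 higher, and without the Zizyphi Fructus library 5 of 36, with 30 higher and 1 lower. With the trends on GC content and transcript length removed 18 of 36 did, 17 being lower and 1 higher. Of 192 counts without a library, 106 did, 74 were lower and 12 higher. Of 378 calls of named genes, 0 were lost with other size factors, 0 with the block, 5 with the DESeq2 Wald test and 16 with no filter, and 30 of 354 with the groups fitted alone. The replicate block within library sets ended 2 of 207. Leaving out a library ended 104 of 1805, and no call reversed in any of these. Where the groups were fitted alone or a library was left out, fewer libraries entered the fit. Between the libraries of Zizyphi Fructus medium dose the chi-square per degree of freedom was 646, against a median of 4.54 over 48 pairs of replicates. All groups share one model, so the spread of that pair entered the main fit behind every comparison. The cause of the changed counts was otherwise not tested. Depth limits genes near 3 counts, which is 0.082 to 0.17 CPM over these libraries.

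With the compared groups fitted alone the high-dose counts against vehicle were 12 for Zizyphi Fructus, 719 for Citri Unshius Pericarpium, 1712 for Cimicifugae Rhizoma, 25 for Yijung-tang and 112 for Banhasasim-tang. With the compared groups fitted alone the medium-dose counts against vehicle were 1763 for Coptidis Rhizoma, 0 for Zizyphi Fructus, 8 for Citri Unshius Pericarpium, 10 for Cimicifugae Rhizoma, 504 for Bupleuri Radix, 117 for Aconiti Lateralis Radix Preparata, 2 for Yijung-tang and 13 for Banhasasim-tang. With the compared groups fitted alone the low-dose counts against vehicle were 48 for Coptidis Rhizoma, 10 for Zizyphi Fructus, 963 for Citri Unshius Pericarpium, 537 for Cimicifugae Rhizoma, 1072 for Bupleuri Radix, 1166 for Aconiti Lateralis Radix Preparata, 31 for Yijung-tang and 2 for Banhasasim-tang. For high against low dose, or for a pair of extracts at high dose, fitting the groups alone gave 10 for Zizyphi Fructus, 51 for Citri Unshius Pericarpium, 3636 for Bupleuri Radix, 1081 for Aconiti Lateralis Radix Preparata, 316 for Yijung-tang, 5345 for Bupleuri Radix against Aconiti Lateralis Radix Preparata and 1556 for Yijung-tang against Banhasasim-tang. Without Zizyphi Fructus medium replicate 3 the high-dose counts against vehicle were 3390 for Zizyphi Fructus, 4686 for Citri Unshius Pericarpium, 5271 for Cimicifugae Rhizoma, 5170 for Aconiti Lateralis Radix Preparata, 3497 for Yijung-tang and 3015 for Banhasasim-tang. Without Zizyphi Fructus medium replicate 3 the medium-dose counts against vehicle were 5403 for Coptidis Rhizoma, 1515 for Zizyphi Fructus, 2102 for Citri Unshius Pericarpium, 3964 for Cimicifugae Rhizoma, 4550 for Bupleuri Radix, 4078 for Aconiti Lateralis Radix Preparata, 2475 for Yijung-tang and 2106 for Banhasasim-tang. Without Zizyphi Fructus medium replicate 3 the low-dose counts against vehicle were 3046 for Coptidis Rhizoma, 3237 for Zizyphi Fructus, 4846 for Citri Unshius Pericarpium, 4785 for Cimicifugae Rhizoma, 4889 for Bupleuri Radix, 4834 for Aconiti Lateralis Radix Preparata, 3768 for Yijung-tang and 2681 for Banhasasim-tang. For high against low dose, or for a pair of extracts at high dose, leaving out that library gave 229 for Citri Unshius Pericarpium, 378 for Cimicifugae Rhizoma, 3624 for Bupleuri Radix, 1009 for Aconiti Lateralis Radix Preparata, 163 for Yijung-tang, 611 for Banhasasim-tang, 340 for Citri Unshius Pericarpium against Cimicifugae Rhizoma, 5256 for Bupleuri Radix against Aconiti Lateralis Radix Preparata and 647 for Yijung-tang against Banhasasim-tang.

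With the DESeq2 Wald test the medium-dose counts against vehicle were 625 for Citri Unshius Pericarpium, 836 for Yijung-tang and 677 for Banhasasim-tang. With the DESeq2 Wald test the low-dose count against vehicle was 898 for Banhasasim-tang. For high against low dose, or for a pair of extracts at high dose, DESeq2 gave 72 for Citri Unshius Pericarpium and 58 for Yijung-tang. With no filter on low counts the medium-dose counts against vehicle were 607 for Citri Unshius Pericarpium, 787 for Yijung-tang and 582 for Banhasasim-tang. With no filter on low counts the low-dose count against vehicle was 813 for Banhasasim-tang. For high against low dose, or for a pair of extracts at high dose, the absence of a filter gave 44 for Zizyphi Fructus, 74 for Citri Unshius Pericarpium and 98 for Yijung-tang. With the trends on GC content and transcript length removed the high-dose counts against vehicle were 447 for Zizyphi Fructus, 718 for Citri Unshius Pericarpium, 1307 for Cimicifugae Rhizoma and 765 for Yijung-tang. With the trends on GC content and transcript length removed the medium-dose counts against vehicle were 183 for Citri Unshius Pericarpium, 648 for Cimicifugae Rhizoma, 675 for Bupleuri Radix, 648 for Aconiti Lateralis Radix Preparata and 310 for Yijung-tang. With the trends on GC content and transcript length removed the low-dose counts against vehicle were 635 for Coptidis Rhizoma, 464 for Zizyphi Fructus, 886 for Citri Unshius Pericarpium, 983 for Cimicifugae Rhizoma, 978 for Bupleuri Radix, 1167 for Aconiti Lateralis Radix Preparata, 557 for Yijung-tang and 160 for Banhasasim-tang. From low to high dose, removing these trends gave 53 for Citri Unshius Pericarpium. Leaving out each library of the compared groups in turn, the high-dose counts against vehicle ran from 91 to 1862 for Zizyphi Fructus, 458 to 2806 for Citri Unshius Pericarpium, 945 to 3469 for Cimicifugae Rhizoma, 2614 to 4460 for Bupleuri Radix, 1242 to 3083 for Aconiti Lateralis Radix Preparata, 226 to 1948 for Yijung-tang and 808 to 1472 for Banhasasim-tang. Leaving out each library of the compared groups in turn, the medium-dose counts against vehicle ran from 1438 to 3429 for Coptidis Rhizoma, 1515 to 10303 for Zizyphi Fructus, 20 to 984 for Citri Unshius Pericarpium, 127 to 2274 for Cimicifugae Rhizoma, 306 to 2832 for Bupleuri Radix, 226 to 2330 for Aconiti Lateralis Radix Preparata, 49 to 1190 for Yijung-tang and 75 to 951 for Banhasasim-tang. Leaving out each library of the compared groups in turn, the low-dose counts against vehicle ran from 186 to 1508 for Coptidis Rhizoma, 115 to 1689 for Zizyphi Fructus, 427 to 3005 for Citri Unshius Pericarpium, 438 to 2974 for Cimicifugae Rhizoma, 478 to 3035 for Bupleuri Radix, 387 to 2949 for Aconiti Lateralis Radix Preparata, 251 to 2053 for Yijung-tang and 75 to 1284 for Banhasasim-tang. For high against low dose, or for a pair of extracts at high dose, the same ran from 9 to 23 for Citri Unshius Pericarpium, 84 to 106 for Cimicifugae Rhizoma, 269 to 395 for Aconiti Lateralis Radix Preparata, 9 to 13 for Yijung-tang, 94 to 105 for Citri Unshius Pericarpium against Cimicifugae Rhizoma and 149 to 173 for Yijung-tang against Banhasasim-tang.

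For the other results, high against low dose of Citri Unshius Pericarpium gave 37 genes with a replicate block within each library set. The list calls fell from 187 to 98 with an estimated correlation, and the highest Spearman rho between extracts, 0.358 over all genes, was 0.751 over genes called in either extract. The cause of these changes was not tested. Fitting the compared groups alone was not possible for Banhasasim-tang high against low dose, with 1 library each, and where leaving out a library left 1 in a group, that library was assumed to vary like the other groups. For Zizyphi Fructus at medium dose the 0 of edgeR with the groups fitted alone stands beside 1153 genes at an unadjusted p under 0.05 and 7630 by DESeq2 with all libraries.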

Other observations

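Tight junction genes, which seal the gaps between epithelial cells, were lower as a list from low to high dose in 3 extracts. In Banhasasim-tang, with 1 library per dose, 1 of 16 fell, or 3 adjusted over the list alone (list adjusted p = 0.00467), in Aconiti Lateralis Radix Preparata 2 fell both ways (list adjusted p = 0.0192), and in Citri Unshius Pericarpium 0 passed in edgeR, or 1 lower adjusted over the list alone (list adjusted p = 0.0167). These lists passed also at adjusted p = 0.0157, 0.0408 and 0.0384 with an estimated correlation. Genes of glycolysis and the hypoxia response were higher as a list in Yijung-tang, with 0 of 20 past the threshold in edgeR both ways (list adjusted p = 4.26e-06, and 0.0346 with an estimated correlation).

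Mitosis genes were lower than in vehicle at high dose of Aconiti Lateralis Radix Preparata, with 10 of 24 past the threshold, or 13 adjusted over the list alone (list adjusted p = 2.24e-08, and 0.0151 with an estimated correlation). In Banhasasim-tang 4 of 24 were lower, or 6 adjusted over the list alone (list adjusted p = 7.76e-06, and 0.0488 with an estimated correlation). The calls with an estimated correlation ended without vehicle replicate 3, at adjusted p = 0.0586 and 0.142, and that of Banhasasim-tang also without vehicle replicate 2, at adjusted p = 0.0596. Neither list passed from low to high dose, at adjusted p = 0.148 and 0.704. The kinase PLK1 stood at -0.41 at low and -0.46 at high dose with Aconiti Lateralis Radix Preparata, at -0.44 and -0.36 with Banhasasim-tang, at -0.45 and -0.30 with Yijung-tang and at -0.32 and -0.25 with Citri Unshius Pericarpium, as log2 changes from vehicle. Extracts of a set were also compared at medium dose, and differed in 6376 genes for Coptidis Rhizoma and Zizyphi Fructus, 15 for Yijung-tang and Banhasasim-tang, 4 for Bupleuri Radix and Aconiti Lateralis Radix Preparata and 2 for Citri Unshius Pericarpium and Cimicifugae Rhizoma, comparisons chosen after the high-dose results were seen. The 4 were TUBB, SCD, ACSS2 and LPIN1 and the 2 were CYP1B1 and ALDH1A3, all lower in the extract named first, and named after their values were seen. The count of 6376 includes Zizyphi Fructus medium replicate 3.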
